A study of Mus musculus with 4 samples.

How the data were processed

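Testis DNA of 3 Mre11-null mice (a conditional knockout, C57BL/6) was amplified over 1 meiotic break hotspot as 4 overlapping amplicons of about 580 bp. Per the labels' protocols, 576 PCRs of 22 cycles were run per amplicon, each on 50 ng of DNA, with an input equal to 9600000 haploid genomes per amplicon. Products were pooled per amplicon, ligated to indexed adapters and sequenced in 1 run as paired reads of 300 bp with 5% PhiX. Per the submitters' processing notes, fastp 0.23.2, BWA 0.7.17 and the mm10 build were used; the program that called the junctions, its filters and the rule that collapsed read pairs to molecules are not given in the sources used here.

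The authors deposited 1 table per amplicon with a row per deletion junction. Per the file headers, each row holds the count of read pairs, the count of molecules and the count of molecule types behind the junction, the first and last deleted base, the deletion size, the length of inserted bases or microhomology at the join, and 1 or more read sequences. The counts are whole and not normalized. The smallest deletion was 11 bp in 3 of the tables, so shorter deletions were not analysed here. Junctions fell into 425 called within a single alignment, the longest of 100 bp, and 379 called from split alignments. Deletions are placed at their leftmost position where microhomology allows several.

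The sequence of the region was rebuilt from the read sequences, since no genome was used. Each base was taken as the most frequent base of the reads over it, with at least 59 read sequences at every base, and 99.9% of read bases matched. The 4 rebuilt amplicon sequences had 0 differing bases where they overlapped. In 1 row of amplicon 4 the deposited start, 33765057, did not match the deposited size of 263 bp, and the read itself placed the start at 33765051, which was used. In 3 rows the file gave a blunt join where the rebuilt sequence allowed microhomology; the file's value was kept and the sequence's value was an alternative. The gene table used was of GRCm38.p6, the assembly that mm10 represents, and gave gene spans only.

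Rows with the same first and last deleted base were merged into 1 distinct deletion, summing read pairs and molecules. The planned share of reads with a deletion needed reads without one, which the tables do not list, so molecules were given per 1000000 haploid genomes of input. Counts have exact Poisson intervals, shares exact Clopper-Pearson binomial intervals and medians bootstrap intervals of 1000 resamples, all at 95%. These intervals cover counting error only, because PCR copies are not independent molecules. With 1 library per amplicon there is no replicate error, and no test compares conditions.

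Positions were tested by placing each deletion at random inside its amplicon, at least 20 bp from the ends, keeping its length, with 100000 resamples and the largest share of midpoints in a 50-bp bin as the statistic. Microhomology was tested by the same placement with 10000 resamples. Sharing between adjacent amplicons was tested by placing the deletions of the first amplicon of each pair at random in the overlap. Numbers of distinct deletions were compared by exact binomial tests for the 6 pairs of amplicons with Benjamini-Hochberg adjustment; the planned correction for depth could not be made, so equal sampling was assumed. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

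The procedures were tested on simulated data, 100 sets per amplicon with the real deletion lengths. The position test called 2% to 5% of sets without a planted cluster and 93% to 100% of sets with one. The microhomology test called 4% to 8% of sets without an excess and 77% to 95% of sets with one. In 50 sets, the test of overlapping kept ends called 4% without and 76% with a planted overlap, and the test of size periodicity called 8% without and 100% with a planted period. Sets without a planted signal were made by the same random placement, shifting or smoothing that each test compares against. Their rates therefore check the procedures only. They do not show how often real deletions, with edges used many times, would be called falsely.

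Named deletions followed a rule fixed with the tests and most alternatives before the data were examined. Per amplicon it takes the 5 distinct deletions with the most read pairs, the longest, the shortest if of more than 1 read, and the 50-bp bins with the most and the fewest midpoints, and over all amplicons the 5 shared deletions with the most read pairs, ties going to the lower start. Alternatives covered minimum deletion size, read support, counting unit, repeat tracts, merging of near edges, bin width and point used, microhomology length, random placement within 50 bp, distance from the primers, and leaving out each amplicon.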

Results

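Deletions were catalogued at 1 meiotic double-strand break hotspot on mouse chromosome 1, in testis DNA of C57BL/6 mice with a conditional knockout of Mre11, labelled Mre11-null. MRE11, the protein it encodes, is the nuclease of the MRE11-RAD50-NBS1 complex, which processes the DNA ends left by SPO11, the protein that makes meiotic breaks. The hotspot was amplified as 4 overlapping amplicons, and the products from 3 mice were pooled into 1 sequencing library per amplicon. Each amplicon was therefore 1 sample with no replicate. The labels list 0 control libraries, so the values below describe the mutant alone and no effect of the genotype was measured. The 4 amplicons spanned 33764688 to 33765556 of chromosome 1 in the mm10 assembly, a stretch of 869 bp inside the span of the gene Zfp451 (33761541 to 33815602). The nearest genes were Bag2, ending at 33757750, and Gm15455, starting at 33835899. Whether the hotspot lies in an exon or an intron of Zfp451 was not analysed here.

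Amplicon 1 covered 33764688 to 33765262, amplicon 2 covered 33764797 to 33765375, amplicon 3 covered 33764915 to 33765491 and amplicon 4 covered 33764983 to 33765556. All 4 shared a window of 280 bp, 33764983 to 33765262. The deposited tables held 804 deletion junctions supported by 3317 read pairs, which the authors had collapsed to 2038 molecules. Read pairs numbered 486 in amplicon 1, 1063 in amplicon 2, 956 in amplicon 3 and 812 in amplicon 4. Reads without a deletion were not used here, so the sequencing depth of each library is unknown and no share of reads with a deletion could be given. Molecules and read pairs of 1 deletion can be copies from PCR, and every interval below covers counting error only.

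Every library held many different deletions. Distinct deletions, defined by their first and last deleted base, numbered 176 in amplicon 1 (95% exact Poisson interval 151 to 204), 242 in amplicon 2 (212 to 274), 202 in amplicon 3 (175 to 232) and 181 in amplicon 4 (156 to 209). Over the 4 libraries they made 659 distinct deletions, of which 551 were seen in 1 library and 108 in at least 2. Set against the 9600000 haploid genomes put into the PCRs of each amplicon, molecules with a deletion came to 36.1 per 1000000 genomes in amplicon 1 (32.4 to 40.2), 69.4 in amplicon 2 (64.2 to 74.8), 59.1 in amplicon 3 (54.3 to 64.1) and 47.7 in amplicon 4 (43.4 to 52.3). These are not frequencies in the DNA, because the share of the input that was sequenced is unknown and each amplicon could show only deletions lying between its primers. Counting each distinct deletion once gave 18.3, 25.2, 21.0 and 18.9 per 1000000 genomes in amplicons 1 to 4. A deletion was supported by a single molecule in 88, 86, 71 and 66 cases in the same order, and requiring at least 3 reads left 72, 134, 112 and 93 distinct deletions.

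The deletions ranged from 11 to 339 bp, and short and long ones formed separate peaks. Of the 659 distinct deletions, 192 were of up to 50 bp, 169 of 51 to 100 bp, 117 of 101 to 200 bp and 181 of over 200 bp. There were 46 deletions of 151 to 200 bp, against 71 of 101 to 150 bp, 70 of 201 to 250 bp, 79 of 251 to 300 bp and 32 of over 300 bp. The median over all libraries was 87 bp, with quartiles of 44 and 215.5 bp. Medians were 74 bp in amplicon 1 (95% bootstrap interval 62.5 to 91), 71.5 bp in amplicon 2 (65 to 87), 76.5 bp in amplicon 3 (65.5 to 94.5) and 87 bp in amplicon 4 (71 to 118), with overlapping intervals. Deletions of over 200 bp made up 21.6% of the distinct deletions in amplicon 1 (exact binomial interval 15.8 to 28.4), 23.1% in amplicon 2 (18.0 to 29.0), 27.2% in amplicon 3 (21.2 to 33.9) and 27.6% in amplicon 4 (21.3 to 34.7). Weighting by read pairs gave medians of 187 bp in amplicon 4 and 123 bp in amplicon 3, whereas weighting by molecules gave 84 bp in both. Amplicons of 574 to 579 bp set an upper bound on the sizes that could be seen. The longest deletion of each library, from 330 bp in amplicon 3 to 339 bp in amplicon 2, fell well short of it. The filters of the junction caller are not known, so whether longer deletions could be seen was not established.

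**Figure D1:**
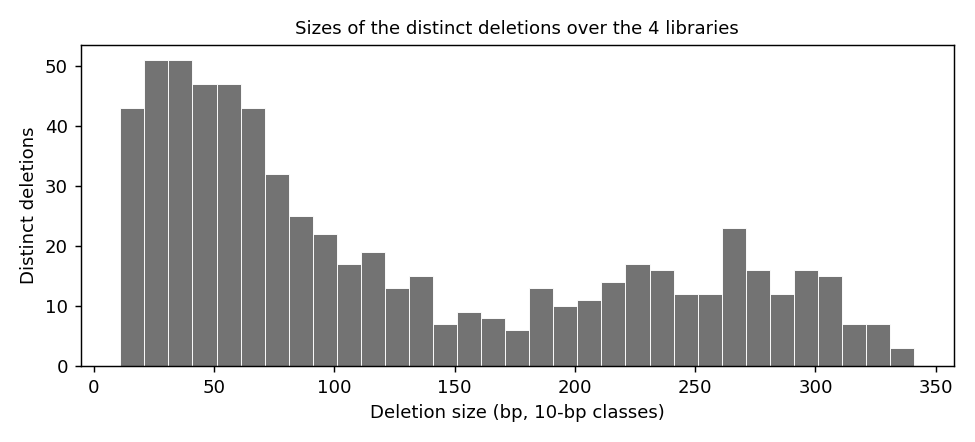
Number of distinct deletions (vertical axis) by deletion size in bp (horizontal axis, classes of 10 bp), over the 4 libraries with each deletion counted once. The classes from 21 to 40 bp held 51 deletions each, the class from 171 to 180 bp held 6 and the class from 261 to 270 bp held 23.

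Deletions were crowded between 33765001 and 33765100. Many also had their midpoint in 33765151 to 33765200, with 35 in amplicon 2, 39 in amplicon 3 and 40 in amplicon 4, against 1 in amplicon 1. Amplicon 1 ended at 33765262, which left limited room for long deletions with a midpoint there, so its count cannot be set against the others. In amplicons 1, 2 and 3 the 50-bp bin with the most deletion midpoints was 33765001 to 33765050, with 67 midpoints (38.1%) in amplicon 1, 76 (31.4%) in amplicon 2 and 62 (30.7%) in amplicon 3. Its sequence is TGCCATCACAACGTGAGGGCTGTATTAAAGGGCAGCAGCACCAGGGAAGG. In amplicon 4 the adjoining bin, 33765051 to 33765100, held the most, 49 midpoints (27.1%), and its sequence is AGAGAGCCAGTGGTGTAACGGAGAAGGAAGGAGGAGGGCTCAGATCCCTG. Deletions of the same lengths placed at random gave a mean of 15.6%, 15.1%, 15.6% and 16.2% in the fullest bin of amplicons 1 to 4. The one-sided permutation p was 1e-05 in each library, the smallest that 100000 resamples can give. Among the bins lying wholly within an amplicon, the emptiest held 0 midpoints in each library. They were 33764701 to 33764750 in amplicon 1, tied with 33765201 to 33765250, and 33764801 to 33764850 in amplicon 2. In amplicon 3 it was 33764951 to 33765000, and in amplicon 4 it was 33765501 to 33765550. These bins lie near amplicon ends, where few deletions between the primers can have a midpoint. The bin empty in amplicon 3 held 16 midpoints in amplicon 1 and 14 in amplicon 2. The start of amplicon 4 lay within 20 bp of the left edge that the other libraries used most, 33765002, which amplicon 4 is thus poorly placed to show.

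**Figure D2:**
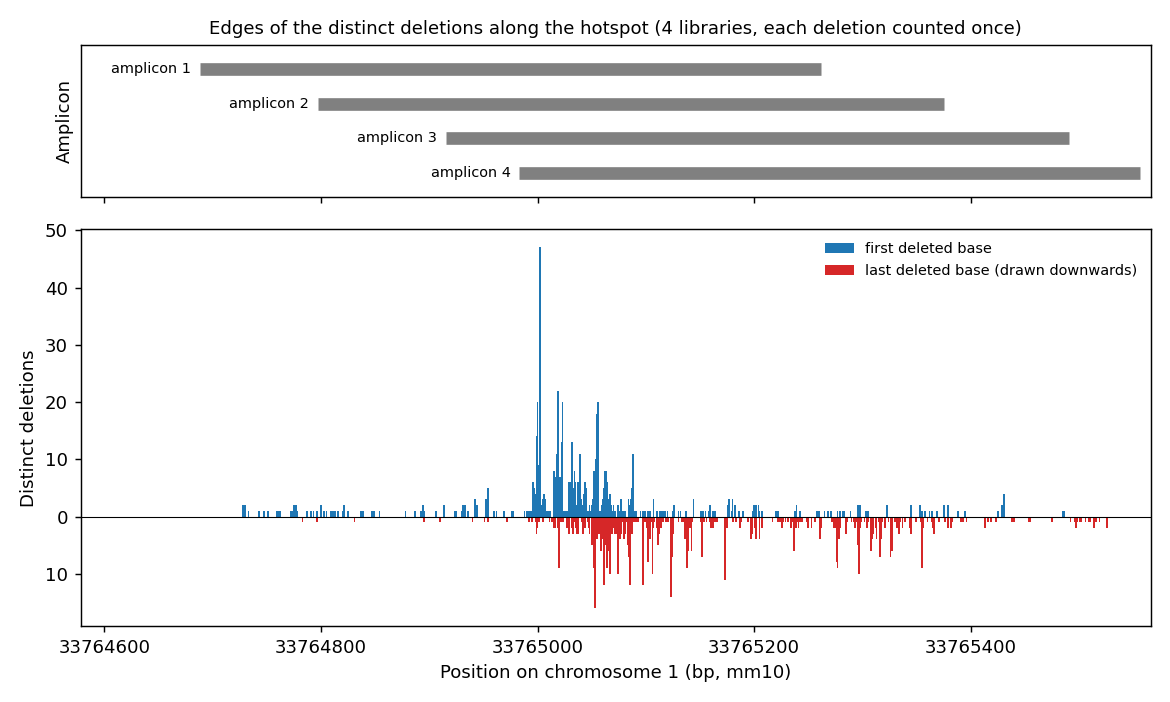
Top, the span of each amplicon on chromosome 1 (bp, mm10). Bottom, the number of distinct deletions that begin (upward bars) or end (downward bars) at each base, over the 4 libraries; the highest bar, at 33765002, stands for 47 deletions and the deepest, at 33765053, for 16.

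A 52-bp deletion of 33765002 to 33765053 had the most read pairs of any deletion found in more than 1 library, 75 in total and 45 molecules, with 9 read pairs in amplicon 1, 29 in amplicon 2 and 37 in amplicon 3. The 275-bp deletion of 33765002 to 33765276 had 11 read pairs in amplicon 2 and 33 in amplicon 3, and the 62-bp deletion of 33765000 to 33765061 had 3, 11 and 27 in amplicons 1, 2 and 3. The 279-bp deletion of 33765019 to 33765297 had 15, 12 and 13 read pairs in amplicons 2, 3 and 4. The 223-bp deletion of 33765055 to 33765277 had 6, 14 and 15 in the same libraries.

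Other much read deletions were found in 1 library or in several. In amplicon 2 the 296-bp deletion of 33765002 to 33765297 led with 40 read pairs and 10 molecules, followed after the 52-bp deletion by 33764953 to 33765020 (68 bp) with 19, and by 33765001 to 33765020 (20 bp) and 33765020 to 33765296 (277 bp) with 17 each. In amplicon 4 the 302-bp deletion of 33765055 to 33765356 led with 39 read pairs and 13 molecules and had 4 bp of microhomology, AGCC. It was followed by 33765023 to 33765297 (275 bp) with 19 read pairs, 33765022 to 33765053 (32 bp) with 18, 33765035 to 33765326 (292 bp) with 16 and 33765024 to 33765326 (303 bp) with 15. Amplicon 3 had 27 read pairs for the 315-bp deletion of 33765002 to 33765316 and 15 for the 216-bp deletion of 33765061 to 33765276. Of these deletions of amplicons 2, 3 and 4, besides the 52-bp one, 33765020 to 33765296 and 33765022 to 33765053 were found in 3 libraries, with 32 and 31 read pairs in all, and 33765001 to 33765020 in 2, with 22; the others were found in 1 library. In amplicon 1 the first 5 deletions had 9 read pairs each. They were the 52-bp deletion above, 33764803 to 33765053 (251 bp), 33765017 to 33765061 (45 bp), 33765022 to 33765053 (32 bp) and 33765031 to 33765124 (94 bp), of which 33765017 to 33765061 was found in 3 libraries, with 31 read pairs in all. The longest deletions were 333 bp in amplicon 1 (33764751 to 33765083), 339 bp in amplicon 2 (33764996 to 33765334), 330 bp in amplicon 3 (33765002 to 33765331) and 333 bp in amplicon 4 (33765023 to 33765355), with 1, 3, 1 and 2 read pairs. The shortest deletion of amplicon 3, 33765007 to 33765019 (13 bp), had 5 read pairs.

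Most joins had microhomology, meaning identical bases at both edges of the deletion of which 1 copy was kept. Among joins without inserted bases, at least 1 bp of microhomology was present in 106 of 172 in amplicon 1 (61.6%, exact binomial interval 53.9 to 68.9), 145 of 228 in amplicon 2 (63.6%, 57.0 to 69.8), 107 of 190 in amplicon 3 (56.3%, 48.9 to 63.5) and 100 of 163 in amplicon 4 (61.3%, 53.4 to 68.9). Deletions of the same lengths placed at random in the same amplicon had it in 44.8%, 44.4%, 44.5% and 44.8%. The two-sided permutation p was 0.0002 in amplicons 1, 2 and 4, the smallest that 10000 resamples can give, and 0.0018 in amplicon 3. The one-sided permutation values were 0.0001 and 0.0009. The test treats distinct deletions as independent, although many share an edge (47 begin at 33765002 over the 4 libraries), so these p may be too small. In amplicons 1 to 4, 49, 71, 48 and 34 joins had exactly 1 bp of microhomology, 28, 43, 35 and 31 had 2 bp, and 29, 31, 24 and 35 had 3 bp or more. The longest was 8 bp in amplicons 1 and 2 and 9 bp in amplicons 3 and 4. In subsets chosen after the values were seen, the excess did not pass the test for deletions of over 100 bp in amplicons 2 and 4 (54.2% against 43.5% at random, permutation p = 0.0666; 54.1% against 43.7%, p = 0.0946). Nor did it for those of up to 100 bp in amplicon 3 (53.0% against 45.2%, permutation p = 0.109) or its deletions of 1 molecule (55.0% against 44.1%, p = 0.109).

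**Figure D3:**
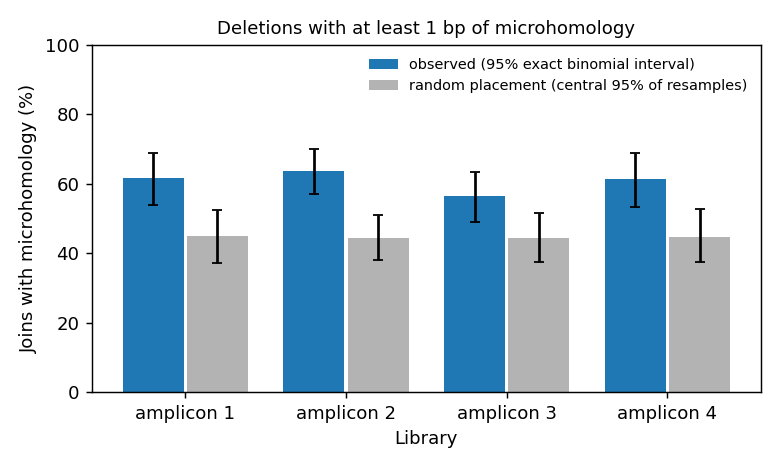
Percentage of joins without inserted bases that had at least 1 bp of microhomology (vertical axis) in each library (horizontal axis). Blue bars are observed shares with 95% exact binomial intervals, and grey bars are the mean of random placement with the range of the central 95% of resamples; observed shares were 56.3% to 63.6% against 44.4% to 44.8%.

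Blunt joins, with neither microhomology nor inserted bases, made up 37.5% of the distinct deletions in amplicon 1 (66 deletions), 34.3% in amplicon 2 (83), 41.1% in amplicon 3 (83) and 34.8% in amplicon 4 (63). Inserted bases were found at 4 deletions in amplicon 1 (2.27%, exact binomial interval 0.623 to 5.72), 14 in amplicon 2 (5.79%, 3.20 to 9.52), 12 in amplicon 3 (5.94%, 3.11 to 10.1) and 18 in amplicon 4 (9.94%, 6.00 to 15.3). The longest insertion was 6 bp in amplicon 1, 20 bp in amplicon 2, 51 bp in amplicon 3 and 21 bp in amplicon 4. No difference in insertions between libraries was tested.

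Adjacent amplicons, which read the same stretch of the same mice's DNA from separate PCRs, recovered some of the same deletions but mostly different ones. Amplicons 1 and 2 shared 33 distinct deletions of the 152 and 186 that lay inside their overlap. Amplicons 2 and 3 shared 41 of 234 and 192, and amplicons 3 and 4 shared 26 of 201 and 165. The shared deletions were 10.8%, 10.6% and 7.65% of all distinct deletions of each pair. Random placement gave 0.574, 0.727 and 0.491 shared deletions on average, with a one-sided permutation p of 0.0001 for each pair, the smallest that 10000 resamples can give. Shifting each edge by up to 5 bp, which keeps the broad crowding of the deletions, gave 3.12, 3.49 and 1.42, with the same p of 0.0001 in each permutation test. This shift also spreads out edges used many times, so it cannot tell the sharing apart from repeated use of the same edges. Of the 391 distinct deletions inside the window common to all 4 amplicons, 302 were found in 1 library, 62 in 2, 24 in 3 and 3 in 4. The numbers of distinct deletions in the overlaps were also compared with an exact binomial test that assumes equal sampling, which gave p = 0.0725 for amplicons 1 and 2, p = 0.0469 for amplicons 2 and 3 and p = 0.0672 for amplicons 3 and 4.

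The number of distinct deletions per shared window did not differ detectably between any 2 amplicons. In the stretch at least 20 bp inside both amplicons, amplicon 2 had 230 and amplicon 3 had 184, a ratio of 1.25 (95% exact interval 1.03 to 1.53), with an exact two-sided binomial p of 0.0269 and a Benjamini-Hochberg adjusted p of 0.161 over the 6 pairs. Amplicons 1 and 2 had 144 and 179, a ratio of 0.804 (0.641 to 1.01; adjusted exact p = 0.175). The other 4 ratios lay between 0.872 and 1.01, with adjusted exact p from 0.611 to 1. Of the 6 pairs, 0 passed after adjustment and 1 had an unadjusted p under 0.05. At least 20 bp inside the window common to all 4 amplicons, from 33765003 to 33765242, the counts were 82, 103, 85 and 94. This window, and that of every pair with amplicon 4, began just after the most used left edge, 33765002. The 47 distinct deletions that begin at 33765002 over the 4 libraries were thus left out there. In their whole overlap amplicons 3 and 4 had 201 and 165 distinct deletions, against 146 and 164 in the trimmed window. The direction of that difference thus changed with the trim. Molecules and read pairs in the shared windows, which can be PCR copies and were not tested, were less even: amplicons 1 and 2 had 298 and 506 molecules and 387 and 688 read pairs, and amplicons 1 and 4 had 158 and 257 molecules and 199 and 369 read pairs. These tests compare libraries of unknown depth and not conditions.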

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

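The values in this part come from the read sequences, which the comparisons above used to rebuild the region and to place the start of 1 deletion, and were computed after the deletions had been examined. Reads with a deletion carried bases that differed from the rebuilt sequence within 10 bp of the join, more than the 3 that a count of 0 allows: 17 in amplicon 1, 4 in amplicon 2, 14 in amplicon 3 and 10 in amplicon 4. This was 4.67, 0.831, 3.47 and 2.86 per 1000 bases, against 1.03, 0.958, 0.779 and 0.988 per 1000 bases elsewhere in the same reads. That limit leaves out the background of the reads, and at the rate elsewhere 3.74, 4.61, 3.14 and 3.45 such bases would be found near the join, so the count of amplicon 2 did not exceed it. There was no control library to set these against, and the difference was not tested.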

How the results depend on the processing

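The subsets of microhomology by deletion length and by molecules, the shifted edges and the weighting by molecules were chosen after the data were seen; the other settings were planned. Of 155 recomputed values, 123 kept their side of the threshold, stayed within their interval or, for counts of distinct deletions, within 1.5 times the reported count, 28 moved, 4 no longer passed their test and 0 changed direction. All 24 settings of the position of deletions, all 15 of sharing between adjacent amplicons and all 12 of the differences between amplicons gave the same call. Of the 123, 20 settings of minimum size or repeat tracts removed no deletion, and the 12 that left out an amplicon could change the adjusted p but not the ratio, so these 20 say nothing about stability. For deletion frequency in amplicons 1 to 4, at least 2 reads gave 29.2, 62.5, 52.9 and 41.7 per 1000000 genomes, at least 3 reads gave 22.8, 54.6, 47.2 and 36.0, each distinct deletion once gave 18.3, 25.2, 21.0 and 18.9, and read pairs gave 50.6, 110.7, 99.6 and 84.6; these follow from counting fewer or more units. Distinct deletions in amplicons 1 to 4 numbered 109, 176, 143 and 123 with at least 2 reads, 72, 134, 112 and 93 with at least 3 reads, and 117, 156, 135 and 141 with edges merged within 3 bp, all below their Poisson intervals. Weighting by read pairs moved the median length to 98 bp in amplicon 2, 123 bp in amplicon 3 and 187 bp in amplicon 4, whereas weighting by molecules gave 68, 84 and 84 bp there; at least 3 reads moved it to 94 bp in amplicon 1 and 109.5 bp in amplicon 3; the cause was not tested. The microhomology excess did not pass for deletions over 100 bp in amplicon 2 (54.2%) and amplicon 4 (54.1%), nor in amplicon 3 for those of up to 100 bp (53.0%) or of 1 molecule (55.0%), all with fewer deletions than the full set. No paired analysis was possible because each group held 1 sample and no comparison between groups of samples was made. Per-read frequencies and per-position settings were not run, as the tables list only junctions; unknown depth limits every comparison of counts between libraries.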

Other observations

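The random placement of long deletions and the tests of overlapping kept ends and of inserted bases were chosen after the result was seen; those of size periodicity were set before the periodicity was computed, although a coarse histogram of sizes had been seen. The 100-bp window with the most midpoints of deletions of up to 100 bp was 33765006 to 33765105. Of the deletions over 200 bp, 27 of 38 in amplicon 1 had an edge in this window (71.1%, exact binomial interval 54.1 to 84.6), 33 of 56 in amplicon 2 (58.9%, 45.0 to 71.9), 41 of 55 in amplicon 3 (74.5%, 61.0 to 85.3) and 41 of 50 in amplicon 4 (82.0%, 68.6 to 91.4). Placing the same deletions at random gave 37.7%, 36.5%, 36.6% and 37.8% in amplicons 1 to 4, and the upper limits of the central 95% of resamples lay between 48.2% and 52.6%. It was the right edge in all 27 in amplicon 1 and the left edge in all 33 in amplicon 2. Amplicon 1 ended at 33765262, which left limited room for a deletion of over 200 bp to begin in the window. Amplicon 2 started at 33764797, which left limited room for 1 to end there. The side of the edge was thus partly set by the amplicon ends. In amplicons 3 and 4 the left edge was the 1 edge that could lie there, since a right edge in the window needs a left edge at or before 33764905, outside both amplicons. The most used left edges, 33765002, 33765019, 33765000, 33765023 and 33765056, began 47, 22, 20, 20 and 20 distinct deletions, and the most used right edges, 33765053 and 33765123, ended 16 and 14. The left edges 33765002 and 33765000 lay just outside the window, so deletions over 200 bp that begin there had no edge in it. The shares above thus depend on where the window falls.

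Across different blunt joins, the kept left end of 1 deletion and the kept right end of another tended to overlap by 2 bases. The kept ends of a single deletion cannot overlap. Among 248 distinct blunt joins, every last kept left base was paired with every first kept right base. Of these pairs, 493 overlapped by 2 bases, 3.34 times the number after shifting edges by up to 10 bp. The permutation p was 0.001, the smallest 2000 resamples can give, and was not adjusted for choosing this overlap from 41 scanned. Each such join has 1 placement, which argues against ambiguous placement of edges. Without the site with the most pairs, 33765054 to 33765055, the fold over all libraries together was 3.13, which argues against that site as the whole cause. With all sites kept, the excess passed in 4 of 4 libraries, so it was not confined to 1 library. The libraries hold DNA of the same mice and share deletions, so these passes are not independent. Shifting also spreads out edges used many times, so it cannot exclude often used edges that happen to lie at this spacing. The overlap of 2 had the most pairs from -20 to 20 bases. Next came -19 with 456 pairs, 2.52 times the number after shifting, with the same permutation p of 0.001. SPO11 cuts leave a stagger of 2 bases, but the scan that showed the overlap also prompted this explanation. Filling in of staggered cuts therefore remains open and untested. With 0 control libraries, joins made during PCR cannot be told apart from joins made in the testis.

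Deletion sizes from 20 to 110 bp were tested for a repeat with a period near that of the DNA helix, with a mixed outcome. Periods further from the helical repeat were not examined. A peak close to the helical repeat therefore follows from the range searched and is not itself a finding. The highest spectral power at periods around the helical repeat lay at 10.9 bp and passed a permutation test against smoothed sizes (p = 0.0215, 339 deletions), as pairs of cuts spaced by whole turns would give. Without the most used left and right edge it still passed narrowly (permutation p = 0.043, 304 deletions). Given the rate of false calls below, this narrow pass does not settle whether those edges were the cause. Other often used edges were kept in, so their part was not tested. On their own, amplicon 2 passed (permutation p = 0.0235), and amplicons 1, 3 and 4 did not (p = 0.535, 0.347 and 0.138). The test called 8% of simulated sets without a period, so the pattern may still be chance.

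Most long inserted sequences matched the hotspot in inverted orientation. Of 21 inserted sequences of 8 bp or more, at 20 distinct deletions, 17 matched the reverse complement of the region exactly and 0 matched it forwards, against 0.048 on average and at most 2 after shuffling the bases, which argues against chance matches. Copying in either orientation alike would not give this split, with an exact binomial p of 0.00781 over 8 separate templates, although how the junction caller treats forward copies is unknown. Primers joined in remain open: 13 of the 17 matches reached outside the outer 25 bp of every amplicon, but 12 touched such an end. Random placement of single matches gave 5.45 (permutation p = 0.0015), but the 12 lay at only 3 of the 8 separate templates. That p counts matches at 1 template as independent, and no random value was computed for templates. Whether templates lay at amplicon ends more often than at random was thus not settled. The insertion AATTTCAAGT at 33765268 to 33765379, a copy of 33765429 to 33765438, was the 1 such junction found in 2 libraries, with 1 read pair in each, and neither there nor for the 16 others, each in 1 library, can a copying event in PCR be told apart from copying in the testis.

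The other 4 inserted sequences, of 21, 33, 33 and 51 bp, were at 3 distinct deletions of amplicon 3, both of 33 bp at the same one. They matched the region in neither orientation, and their origin was not analysed here. These deletions, edges and insertions were picked after their values were seen. No effect of genotype was tested, since all libraries had the same genotype.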
